A study of Mus musculus with 8 samples.

How the data were processed

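Single-cell RNA was measured in 8 libraries of mouse pancreatic tumours, 1 per sort (CAF or immune) and treatment (vehicle, FAKi, MEKi or both), each a pool of 2 to 4 mice of mixed sex by the labels. The deposited matrices hold UMI counts per gene and cell barcode, which the authors left without normalization: every value was checked to be a whole number of at least 1. Per the file headers they were written by Cell Ranger 4.0.0, while the submitters' processing notes name Cell Ranger 2.1.1 with mm10; the aligner settings and the annotation are not given in the sources used here. The files list 32285 gene IDs, of which 32235 were matched by ID to GENCODE vM21 for positions.

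Cells with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs were kept. Doublets were scored per library by a Scrublet-type simulation with an expected rate of 0.8% per 1000 barcodes; where the automatic threshold marked under 0.5% or over 25% of a library, as in the CAF libraries, the top expected share by score was removed. The libraries of each sort were clustered together on 2000 variable genes, 30 principal components and 20 neighbours with Leiden resolution 1 and no batch integration (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0). A cluster was named where at least 3 markers of a class were detected in its cells and its marker score reached 0.5. It still stayed unnamed where its top 10 genes held more markers of another class, or where an unrelated class scored nearly as high. A cluster with low UMI counts and no own marker among those genes was left unnamed too. Shares of cells carry Clopper-Pearson 95% intervals. Cells were called female or male from Xist and Y-linked genes, which gives the values for each sex where at least 20 cells of that sex were present.

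UMIs were summed per class and library for 6 classes (fibroblast, macrophage, neutrophil, T cell, CD8 T cell and B cell) and scaled to CPM of the sum, with 0.5 UMIs added to each sum for folds. Intervals of folds are exact Poisson intervals, conditional on the 2 sums. With 1 library per group no test between treatments was possible: no p-values are given, and fixed rules of size are used instead. The 5 contrasts were each treatment over vehicle and the combination over each single agent. In all, 38 gene lists were fixed before the data were examined, as were the rules for named genes and the alternatives, except where the text says otherwise. A list member was measured with at least 20 UMIs in either library of a contrast. Random lists were drawn 10000 times from 20 expression bins with seed 1. Genes named outside the lists were the 10 highest and 10 lowest per class and contrast over vehicle with at least 100 UMIs, detection in at least 5% of cells, an interval excluding 1 and no carry-over ratio above 10, and of these the ones with a known role are given; from each list at most the 4 members with the largest fold may be named. The share of cells in cycle was taken after thinning cells to 2000 UMIs in fibroblasts and 1000 in immune cells.

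Genes whose last 500 transcript bases share at least 20% of their 31-mers with another gene were marked as having a near-identical copy: 1142 of 17326 tested genes (6.59%). Their counts depend on how reads that map to both copies were assigned, and they are left out of the genes named with values.

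The rules were tested on simulated data. With 14991 genes at the depth of MEKi fibroblasts, 52% of genes with a true fold of 1.5 passed the size rule, 96% with a fold of 2 and 100% with a fold of 4, against 0.717% of unchanged genes, and 94.9% of intervals held the true fold. At the depth of combination macrophages (11800 genes) these values were 58%, 92%, 100%, 1.03% and 95.4%.

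The alternatives tried were other filters on cells, kept doublets, Leiden resolutions 0.5 and 2, list minimums of 1 and 100 UMIs, edgeR 4.0.16 TMM (R 4.3.3) and median-of-ratios scaling, the mean of per-cell CPM, thinned cells, female or male cells alone, single clusters with at least 100 cells per library, and other thresholds for cells in cycle. Clustering and naming without digestive-enzyme genes, and lists without near-identical copies, were added after the data were seen. Figures were drawn with matplotlib 3.10.9. Left out were classes with under 200 cells in any library of a sort other than the 4 planned ones, since their sums are thin.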

Results

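The tumours came from KPPC mice, in which the pancreas carries mutant Kras and lacks p53, and were collected at day 14 from mice given vehicle, an inhibitor of focal adhesion kinase (FAKi), an inhibitor of the kinase MEK (MEKi) or both (called the combination). Neither the compounds nor the doses are named in the labels. From each of the 4 arms 1 library held sorted cancer-associated fibroblasts (CAFs, CD45-, CD31-, EPCAM- and PDPN+) and 1 held sorted CD45+ immune cells, which makes 8 single-cell RNA libraries, each pooled from 2 to 4 mice. The series title places the work in the question of how FAK inhibition alters the tumour stroma alongside inhibition of the MAPK pathway. The CAF libraries held 122746862 (vehicle), 120821758 (FAKi), 102967119 (MEKi) and 111515102 (combination) unique molecular identifiers (UMIs), of which 6335, 9788, 7506 and 8631 cells were kept. The immune libraries held 93238846, 110444233, 97141193 and 97442411 UMIs in the same order, with 9263, 15883, 12129 and 10862 cells kept. Median UMIs per kept cell were 15467 in the vehicle CAF library against 9727.5, 11669 and 11081 in the treated ones, and 6665 against 3840, 5455 and 6213.5 in the immune libraries. Female cells made up 65.7%, 1.89%, 45.1% and 85.0% of the cells with a sex call in the CAF libraries and 63.7%, 0.275%, 70.9% and 67.1% in the immune libraries, so that both FAKi libraries were almost all male. With 1 library per arm there are no replicates: values carry exact 95% intervals, given in parentheses, that cover counting error and not the variation between mice. A gene counts as higher or lower where its fold is at least 1.5 and its interval excludes 1. For a gene list, the median log2 fold of its measured members is given with its percentile among 10000 random lists matched on expression, where 0 means below all of them and 100 above all. Expression is given as CPM, the UMIs of a gene summed over a cell class and scaled to a common total. Gene IDs are those of the files, and gene positions refer to mm10.

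To ask which cells each sort held under each treatment, cells were clustered and named by markers. Fibroblast-like cells made up 73.6% (72.5 to 74.6) of the vehicle CAF library, 92.4% (91.9 to 92.9) under FAKi, 98.1% (97.8 to 98.4) under MEKi and 97.6% (97.2 to 97.9) under the combination. Mesothelial-like cells, which line the abdominal cavity and organs, were 16.4% (15.5 to 17.4) of the vehicle library and 1.08% (0.887 to 1.31), 1.17% (0.941 to 1.44) and 0.788% (0.612 to 0.998) of the treated ones. Immune cells that passed the gate were, in the same order, 5.15% (4.61 to 5.72), 0.838% (0.667 to 1.04), 0.213% (0.122 to 0.346) and 0.463% (0.331 to 0.631). The fibroblast clusters also differed. In vehicle, cluster 3 (Lrrc15, Postn, Fbn2) held 24.5% of fibroblasts, cluster 4 (Inmt, Pcolce2, Gsn) 18.7% and cluster 13 (Sfrp4, Lum, Ly6c1) 15%. Under FAKi, clusters 1 and 2, both led by the imprinted gene Peg3 with Ptn, held 21.5% and 20.4%, and cluster 3 held 17.3%. Cluster 0, led by Col14a1, Dpt and Clec3b, held 21.6% of fibroblasts under MEKi and 22.0% under the combination.

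In the immune sort, macrophage-like cells were 8.09% (7.54 to 8.66) of vehicle cells, 7.59% (7.18 to 8.01) under FAKi, 3.42% (3.11 to 3.76) under MEKi and 2.22% (1.95 to 2.51) under the combination. In male cells alone the macrophage shares were 7.49%, 10.8%, 2.78% and 2.11%, so the order of vehicle and FAKi turns with sex. Neutrophil-like cells were 6.98% (6.59 to 7.39) under FAKi, against 1.27% (1.06 to 1.52) in vehicle, 0.833% (0.679 to 1.01) under MEKi and 1.3% (1.09 to 1.53) under the combination. Plasma cells were 0.497% (0.364 to 0.662) of vehicle cells and 3.48% (3.2 to 3.77), 1.36% (1.16 to 1.58) and 2.17% (1.91 to 2.46) of treated ones. Migratory dendritic cells, which carry antigen to lymph nodes, were 1.92% (1.65 to 2.22) in vehicle and 0.730% (0.604 to 0.875), 1.24% (1.05 to 1.45) and 0.690% (0.543 to 0.865) with treatment. T cells were 46.3% (45.3 to 47.3), 41.7% (40.9 to 42.5), 52.8% (51.9 to 53.7) and 33.3% (32.4 to 34.2), and B cells 38.3% (37.3 to 39.3), 36.0% (35.3 to 36.8), 32.9% (32.1 to 33.7) and 25% (24.2 to 25.9). The combination library held 32.2% (31.4 to 33.1) unnamed cells, in clusters led by digestive-enzyme genes of pancreatic acinar cells. When clusters were built and named without those genes, a choice made after the data were seen, unnamed cells were 3.02% of the combination library, B cells 38.5%, T cells 48.9% and macrophages 2.38%.

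Among T-cell-like and NK-like cells, CD8 T cells were 35.9% (34.4 to 37.3) in vehicle, 27.0% (26.0 to 28.1) under FAKi, 32.0% (30.9 to 33.2) under MEKi and 29.4% (27.9 to 30.9) under the combination. CD4 T cells were 57.8%, 59.8%, 58.9% and 58.1%. Group 2 innate lymphoid cells (ILC2) were 0.716% (0.487 to 1.01) in vehicle and 0.345% (0.219 to 0.517), 1.48% (1.20 to 1.81) and 3.56% (2.98 to 4.21) with treatment. Natural killer cells, which kill without prior priming, were 0.970% (0.700 to 1.31) in vehicle and 0.705% (0.519 to 0.937), 1.02% (0.789 to 1.29) and 1.66% (1.27 to 2.12) under FAKi, MEKi and the combination. Regulatory T cells were 2.15% in vehicle and 0.390% under FAKi at the resolution used, but the order turned at other resolutions, so no direction is given. The combination shares rest on 3619 T cells, since many cells of that library stayed unnamed. With classes named without digestive-enzyme genes it held 5313 T cells, and 1710 CD8 T cells in place of 1082.

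**Figure D1:**
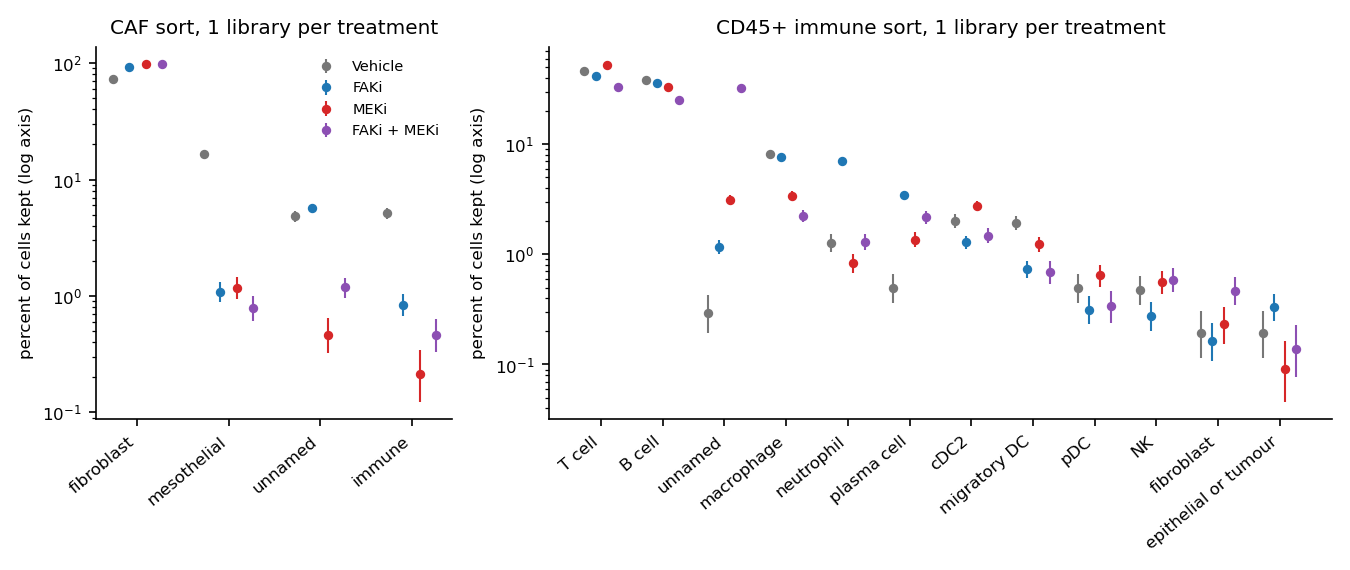
Share of cells kept per library (percent, log axis) for the cell classes of the CAF and immune sorts, as dots with exact 95% intervals for vehicle (grey), FAKi (blue), MEKi (red) and the combination (purple). Mesothelial cells lie at 16.4% in vehicle and near 1% in the treated libraries, neutrophils at 6.98% under FAKi, and macrophages at 2.22% under the combination.

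To ask how fibroblasts differed under FAK inhibition alone, 9046 FAKi cells were set against 4660 vehicle cells. FAKi fibroblasts held less RNA of inflammatory CAF genes, of genes induced by type I interferon and of genes downstream of ERK. In the inflammatory CAF list, of cytokines and secreted immune factors, 14 of 17 measured members were lower and 0 higher (median log2 fold -1.53, percentile 0). The median was -1.27 in male cells alone, and from -0.74 to -0.39 within the 3 largest clusters. These clusters (0, 1 and 2) held only 106, 493 and 297 vehicle cells. Ccl7 (ENSMUSG00000035373, chromosome 11, 82045712 to 82047525), a monocyte-attracting chemokine, was at 10.7 against 68.4 CPM, log2 fold -2.67 (-2.77 to -2.58). The hyaluronan synthase Has2 was at 4.95 against 20.1 CPM, log2 fold -2.02 (-2.17 to -1.87). Clec3b was at 242 against 929 CPM, log2 fold -1.94 (-1.96 to -1.92). In the type I interferon list 12 of 14 measured members were lower and 0 higher (median log2 fold -1.16, percentile 0), and -1.55 in male cells. Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), a ubiquitin-like protein induced by interferon, was at 6.97 against 59.7 CPM, log2 fold -3.10 (-3.22 to -2.98), and Ifit1 at 5.46 against 20.3 CPM, log2 fold -1.89 (-2.04 to -1.75). The chemokine list (9 of 11 lower, 0 higher, median -1.53) and the NF-kB list (7 of 13 lower, 0 higher, median -0.67) were lower too, with Cxcl1, which attracts neutrophils, at 21.4 against 69.2 CPM, log2 fold -1.70 (-1.77 to -1.62). Ccl2 was at 21.8 against 54.8 CPM, log2 fold -1.33 (-1.41 to -1.26). The list of immune carry-over genes was lower as well (5 of 10 lower, 0 higher, median -0.60), and immune cells make several of the listed chemokines.

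ERK output genes, which read out the kinase below MEK, had 11 of 20 measured members lower and 1 higher under FAKi (median log2 fold -0.90, percentile 0; -0.60 in male cells), with Phlda1 at 59.4 against 158 CPM, log2 fold -1.41 (-1.46 to -1.37). The cell cycle gene Ccnd1 was at 4.61 against 11.9 CPM, log2 fold -1.36 (-1.53 to -1.20). Targets of YAP and TEAD, which respond to tension, had a median of -0.66 (6 of 11 lower, 0 higher; -0.51 in male cells), including Amotl2, -1.34 (-1.40 to -1.28) and Ccn2, -0.70 (-0.73 to -0.67). Focal adhesion genes had a median of -0.53 (6 of 16 lower, 0 higher), with the adaptor paxillin (Pxn) at 16.6 against 34.6 CPM, log2 fold -1.06 (-1.15 to -0.97). Basement membrane genes had a median of -0.47 (5 of 11 lower), while the collagen list lay closer to vehicle at -0.21 (5 of 17 lower, 12 within 1.5-fold), its lowest member being fibronectin (Fn1) at 994 against 2251 CPM, log2 fold -1.18 (-1.19 to -1.17). Contractile myofibroblast genes were mostly within 1.5-fold (9 of 12, median -0.11, percentile 16.8). TGF-beta response genes had 9 of 12 within 1.5-fold and a median of -0.14, which was 0.15 in male cells.

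Genes of antigen presentation and complement were lower in FAKi fibroblasts: MHC class I genes had a median of -0.61 (6 of 11 lower, 0 higher), MHC class II genes -1.10 (4 of 7 lower, but 0.04 within cluster 0) and complement genes -0.66 (4 of 7 lower). The antigen-presenting CAF list, which shares genes with mesothelium, had 8 of 9 members lower (median -1.37), beside the lower mesothelial share given above. In male cells the medians of these 4 lists were -0.67, -0.94, -0.73 and -1.27. Cell cycle genes had 11 of 19 lower (median -0.91), with Mki67 at 1.28 against 6.61 CPM, log2 fold -2.37 (-2.67 to -2.08). With cells thinned to 2000 UMIs, the share with at least 2 UMIs of the list differed little: 5.72% (5.07 to 6.43) in vehicle, 5.99% (5.51 to 6.50) under FAKi and 5.92% (5.39 to 6.49) under MEKi. At 4 UMIs, an alternative, it was 0.888%, 0.289% and 0.262%. Among the genes most above vehicle, Zbtb16 (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222), a transcription factor, was at 66.6 against 8.67 CPM, log2 fold 2.94 (2.83 to 3.06). Tsc22d3 (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), a glucocorticoid-induced regulator, was at 269 against 45.4 CPM, log2 fold 2.57 (2.52 to 2.62). Rgs2 (ENSMUSG00000026360, chromosome 1, 143999338 to 144004161), which damps G protein signalling, was at 294 against 46.5 CPM, log2 fold 2.66 (2.61 to 2.71). Tdo2 (ENSMUSG00000028011, chromosome 3, 81957090 to 81976202), which breaks down tryptophan, was at 16.0 against 1.99 CPM, log2 fold 3.0 (2.77 to 3.26). Their log2 folds in male cells were 3.90, 2.64, 2.53 and 2.72. The amino acid transporter Slc7a5 (ENSMUSG00000040010, chromosome 8, 121881150 to 121907694) was at 2.03 against 15.5 CPM, log2 fold -2.93 (-3.16 to -2.71). The peptide hormone gene Apln (ENSMUSG00000037010, chromosome X, 48025146 to 48034853) was at 2.43 against 15.8 CPM, log2 fold -2.70 (-2.91 to -2.49). Beside these, epithelial carry-over genes had 5 of 11 members higher and acinar carry-over genes 10 of 16.

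The same comparison for MEK inhibition alone (7367 fibroblasts) gave lower ERK output, TGF-beta response and contractile genes. Of the ERK output list, 13 of 20 measured members were lower and 0 higher (median log2 fold -0.85, percentile 0). Etv4 (ENSMUSG00000017724, chromosome 11, 101769742 to 101785371), a transcription factor induced by ERK, was at 0.524 against 9.29 CPM, log2 fold -4.13 (-4.61 to -3.72). The ERK phosphatase Dusp4 was at 0.747 against 6.37 CPM, log2 fold -3.08 (-3.48 to -2.72). Its relative Dusp6 was at 5.57 against 29.4 CPM, log2 fold -2.40 (-2.54 to -2.26), and the feedback inhibitor Spry4 at 5.18 against 25.5 CPM, log2 fold -2.30 (-2.45 to -2.15). TGF-beta response genes had 10 of 12 members lower (median -1.0, percentile 0), including the ligand Tgfb1 at 20.4 against 75.3 CPM, log2 fold -1.88 (-1.96 to -1.81). The latent TGF-beta binding protein Ltbp2 was at 14.5 against 86.2 CPM, log2 fold -2.57 (-2.65 to -2.48). Timp1 was at 168 against 611 CPM, log2 fold -1.87 (-1.89 to -1.84). Contractile genes had 10 of 12 lower (median -0.87), with smooth muscle actin Actg2 at 2.51 against 13.6 CPM, log2 fold -2.44 (-2.66 to -2.23). Thy1 was at 221 against 586 CPM, log2 fold -1.41 (-1.43 to -1.38) and transgelin (Tagln) at 157 against 308 CPM, log2 fold -0.97 (-1.0 to -0.94). Lrrc15 (ENSMUSG00000052316, chromosome 16, 30269302 to 30283256), a surface protein of myofibroblast-like CAFs, was at 1.82 against 43.1 CPM, log2 fold -4.57 (-4.81 to -4.34). Vehicle fibroblasts also held a cluster with Lrrc15 among its leading genes, with 1143 cells against 70 under MEKi.

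Matrix genes split under MEKi. Tnc (ENSMUSG00000028364, chromosome 4, 63959785 to 64047015), tenascin C, was at 15.6 against 213 CPM, log2 fold -3.77 (-3.85 to -3.69). Col12a1 was at 82.2 against 422 CPM, log2 fold -2.36 (-2.40 to -2.32), while 12 of 17 members of the collagen list were within 1.5-fold (median -0.44). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), osteopontin, was at 16.6 against 792 CPM, log2 fold -5.57 (-5.65 to -5.50), with -6.56 in male and -4.92 in female cells. Beside these values, all 10 immune carry-over genes measured were lower (median -2.43), as were 9 of 10 epithelial ones (median -2.04). YAP and TEAD targets went both ways (4 of 11 lower, 2 higher), with Ccn2 at 59.7 against 283 CPM, log2 fold -2.24 (-2.29 to -2.20). Tissue factor F3 was at 210.0 against 84.4 CPM, log2 fold 1.31 (1.27 to 1.36). Genes of cholesterol synthesis had 8 of 11 lower (median -1.09, but 0.05 within cluster 0), including Cyp51 at 12.2 against 49.7 CPM, log2 fold -2.03 (-2.13 to -1.93) and Sqle at 2.01 against 8.30 CPM, log2 fold -2.04 (-2.29 to -1.81). Chemokines had 8 of 11 lower (median -2.32), and Ccl2 stood at 12.1 against 54.8 CPM, log2 fold -2.18 (-2.28 to -2.09). The cytokine Il6 was at 45.1 against 24.2 CPM, log2 fold 0.90 (0.82 to 0.98).

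Under MEKi the inflammatory CAF list as a whole lay near vehicle (7 of 17 lower, 3 higher, median -0.12, percentile 19.8), as did the type I interferon list (median 0.16). Immediate early genes had 6 of 14 higher (median 0.51), with Nr4a1 at 207 against 82.1 CPM, log2 fold 1.33 (1.29 to 1.37). Fos was at 2032 against 999.6 CPM, log2 fold 1.02 (1.01 to 1.03); tissue dissociation is known to induce these genes. Zbtb16 was higher, as under FAKi, at 63.4 against 8.67 CPM, log2 fold 2.87 (2.75 to 2.99). Angptl4 (ENSMUSG00000002289, chromosome 17, 33773750 to 33781830), an inhibitor of lipoprotein lipase, was at 216 against 40.4 CPM, log2 fold 2.41 (2.36 to 2.47). Medians for female and male cells apart were -0.82 and -0.84 for ERK output, -0.92 and -0.91 for contractile genes, and -0.97 and -0.83 for TGF-beta response.

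Fibroblasts under the combination (8421 cells) had lower contractile, TGF-beta response and ERK output genes than in vehicle: contractile genes had 9 of 12 members lower and 1 higher (median -1.05, percentile 0), TGF-beta response genes 6 of 12 lower (median -0.59) and ERK output genes 10 of 20 lower (median -0.62). Etv4 was at 0.396 against 9.29 CPM, log2 fold -4.53 (-5.06 to -4.08). Dusp4 (ENSMUSG00000031530, chromosome 8, 34807297 to 34819894) was at 0.355 against 6.37 CPM, log2 fold -4.15 (-4.71 to -3.66). Smooth muscle actin Acta2 was at 81.4 against 266 CPM, log2 fold -1.71 (-1.75 to -1.67) and Thy1 at 199 against 586 CPM, log2 fold -1.56 (-1.59 to -1.54). Spp1 was at 21.4 against 792 CPM, log2 fold -5.21 (-5.28 to -5.15), with -2.86 in male and -7.37 in female cells. Cell cycle genes had 11 of 19 lower (median -2.04), with Mki67 at 0.157 against 6.61 CPM, log2 fold -5.36 (-6.25 to -4.67). E2f8 (ENSMUSG00000046179, chromosome 7, 48866429 to 48881596), a cell cycle transcription factor, was at 0.396 against 7.82 CPM, log2 fold -4.28 (-4.81 to -3.83). The thinned share of cells with at least 2 UMIs of the list was 5.39% (4.91 to 5.90) against 5.72% in vehicle, and 0.132% against 0.888% at 4 UMIs. Within cluster 0 the cell cycle median was 0.24 and within cluster 2 it was 0.09, and the ERK output median was -0.20 and -0.03, so both lists differed less inside these clusters. They held only 106 and 297 vehicle fibroblasts. Antigen-presenting CAF genes had 8 of 9 lower (median -1.94), with the acute phase gene Saa3 at 9.71 against 138 CPM, log2 fold -3.83 (-3.92 to -3.73). Zbtb16 was at 108 against 8.67 CPM, log2 fold 3.64 (3.53 to 3.76). Pdk4 (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309), which limits glucose oxidation, was at 22.1 against 3.5 CPM, log2 fold 2.65 (2.47 to 2.84). All 16 acinar carry-over genes measured were higher (median 5.40); beside them Sycn (ENSMUSG00000084174, chromosome 7, 28540885 to 28542209), a zymogen granule protein, was at 12.9 against 0.183 CPM, log2 fold 6.09 (5.39 to 7.02). Reg2 (ENSMUSG00000023140, chromosome 6, 78395623 to 78408106) was at 55.4 against 1.71 CPM, log2 fold 5.01 (4.77 to 5.28).

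**Figure D2:**
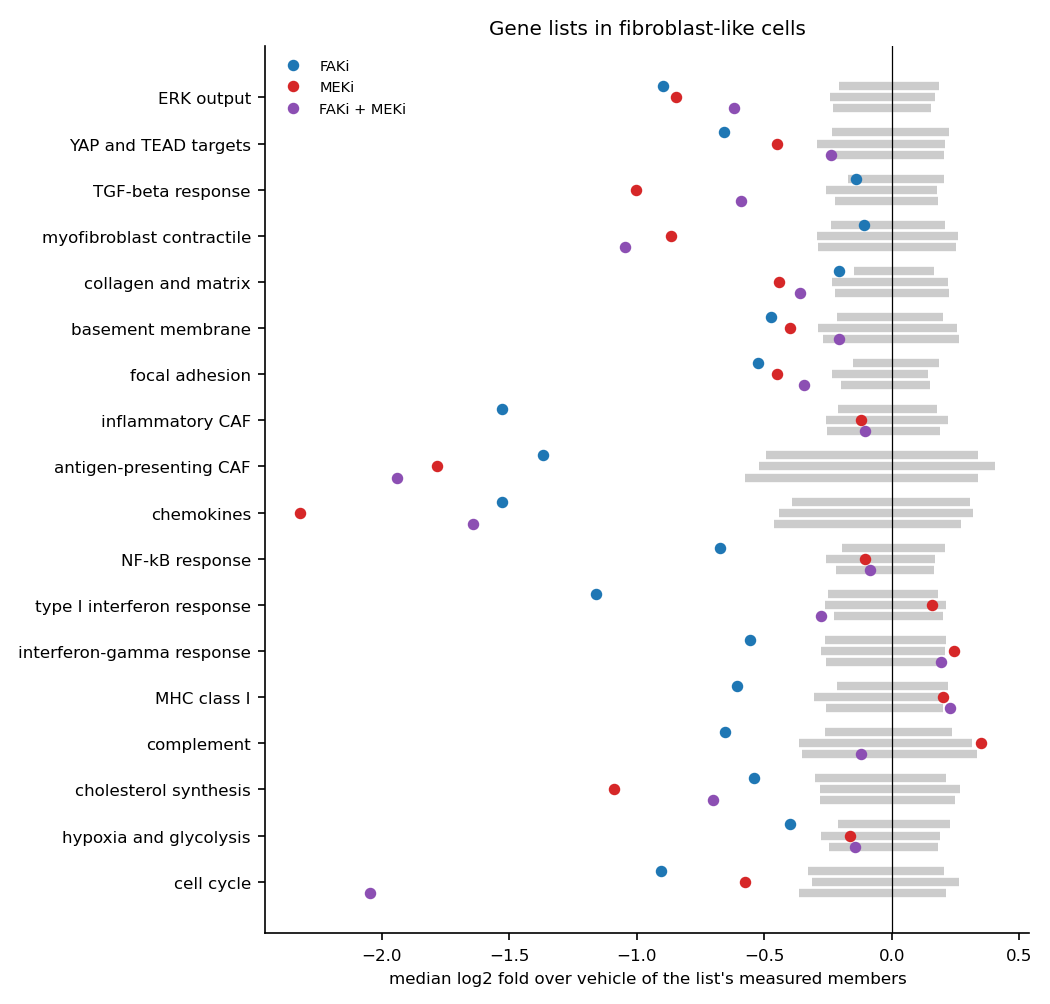
Median log2 fold over vehicle (horizontal axis) of gene lists in fibroblast-like cells, as dots for FAKi (blue), MEKi (red) and the combination (purple), with grey bars over the central 95% of matched random lists. Inflammatory CAF genes lie at -1.53 under FAKi and near 0 in the other arms, while contractile genes lie at -0.87 under MEKi and -0.11 under FAKi.

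Set against FAKi alone, fibroblasts under the combination had higher inflammatory CAF genes (10 of 17 higher, 3 lower, median 0.95), type I interferon genes (11 of 14 higher, median 0.92), MHC class I genes (9 of 11 higher, median 0.84) and complement genes (5 of 7 higher, median 0.75, but -0.29 within cluster 0). Lower against FAKi were contractile genes (8 of 12, median -0.96, but 0.40 within cluster 2) and TGF-beta response genes (7 of 12, median -0.68). Of ERK output genes 9 of 20 were lower and 3 higher (median -0.44). Against MEKi alone, ERK output lay at 0.10, inflammatory CAF at -0.03, type I interferon at -0.44, cholesterol synthesis at 0.42 and cell cycle at -1.32 (11 of 19 lower). The log2 fold of the combination minus the sum of the single-agent log2 folds, which is 0 if the agents add up, had a median over all genes of 0.01. It was 1.69 for inflammatory CAF genes, 2.03 for chemokines, 0.81 for type I interferon, 0.79 for cholesterol synthesis and 0.68 for ERK output, so these lists lay higher than the sum of both single agents. All the folds share the single vehicle library. A list that stood high in that pool alone would give a value above 0 without any interaction of the agents. Chemokines and ERK output genes lay below vehicle in every arm, so for them this cannot be told apart. A list that stood low in the FAKi pool alone would also give a value above 0. Inflammatory CAF and type I interferon genes were low under FAKi and near vehicle under MEKi, so for them that cannot be told apart. With 1 pool per arm, none of these departures is separable from a difference between pools. The departure was 0.18 for contractile genes, 0.21 for collagens and -0.17 for the cell cycle.

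How macrophages differed was asked on 749 vehicle, 1205 FAKi, 415 MEKi and 241 combination cells, which formed 1 cluster. Among the genes furthest below vehicle under FAKi, Cd5l (ENSMUSG00000015854, chromosome 3, 87357881 to 87371073), a secreted macrophage protein, was at 0.163 against 45.1 CPM, log2 fold -7.89 (-10.40 to -6.56) with 3 UMIs under FAKi. The scavenger receptor Marco (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024) was at 1.79 against 99.0 CPM, log2 fold -5.77 (-6.33 to -5.29). Alox15 (ENSMUSG00000018924, chromosome 11, 70344152 to 70352031), a lipoxygenase, was at 8.95 against 223 CPM, log2 fold -4.64 (-4.87 to -4.41). Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) was at 64.9 against 1580.1 CPM, log2 fold -4.61 (-4.69 to -4.52). It was lower in every treated library in 4 cell classes, though in T and B cells carry-over from macrophages is not excluded. In male cells the log2 folds of Marco, Alox15 and Saa3 were -5.84, -3.21 and -4.32. Folr2 was at 16.5 against 80.9 CPM, log2 fold -2.29 (-2.48 to -2.12) and the cytokine Il6 at 35.5 against 130.4 CPM, log2 fold -1.88 (-2.00 to -1.75). Higher under FAKi was the adhesion molecule Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688) at 43.3 against 10.3 CPM, log2 fold 2.07 (1.84 to 2.30). Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), a glucocorticoid-induced chaperone partner, was at 127 against 29.9 CPM, log2 fold 2.09 (1.96 to 2.23). The neutrophil chemokine Cxcl3 was at 109 against 24.3 CPM, log2 fold 2.16 (2.02 to 2.31). Of the cell cycle list 16 of 19 measured members were lower and 0 higher (median log2 fold -1.03, percentile 0); the type I interferon list had 5 of 14 lower (median -0.29, -0.58 in male cells) and complement 6 of 7 lower (median -1.45, -0.64 in male cells). Stromal carry-over genes had all 7 members lower under FAKi (median -4.10, -1.39 in male cells). All 7 were lower under MEKi too, and 6 of 7 under the combination. Of the chemokines, 11 of 13 were within 1.5-fold, and ERK output genes had 7 of 18 lower (median -0.49, -0.18 in male cells).

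MEK inhibition went with lower hypoxia, matrix enzyme and ERK output genes and higher interferon genes in macrophages. Hypoxia and glycolysis genes had 10 of 12 members lower (median -1.23, percentile 0), with the glucose transporter Slc2a1 at 17.0 against 56.5 CPM, log2 fold -1.73 (-1.99 to -1.48). Cholesterol synthesis had 10 of 11 lower (median -0.87), ERK output 11 of 18 (median -0.63) with Dusp6 at 17.3 against 44.4 CPM, log2 fold -1.36 (-1.63 to -1.11), and matrix remodelling enzymes 7 of 10 (median -1.30). The collagen list also lay lower in these macrophages, at -3.84 (-3.62 with absent genes at the bound of their interval), as did stromal carry-over genes. For the matrix enzyme list, carried-over stromal RNA was not separated from a change in macrophages. Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), macrophage elastase, was at 104 against 919.8 CPM, log2 fold -3.14 (-3.24 to -3.04). Mmp9 (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850), a gelatinase, was at 74.4 against 6.96 CPM, log2 fold 3.41 (3.15 to 3.70). Ccl17 (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036), which attracts T cells, was at 60.6 against 518 CPM, log2 fold -3.09 (-3.23 to -2.97). Ccl24 was at 23.4 against 175 CPM, log2 fold -2.90 (-3.12 to -2.69). Of genes tied to tumour-promoting macrophages, arginase Arg1 was at 349 against 1307 CPM, log2 fold -1.91 (-1.96 to -1.85) and Spp1 at 171 against 513 CPM, log2 fold -1.58 (-1.67 to -1.50). Retnla was at 3289 against 1474 CPM, log2 fold 1.16 (1.14 to 1.18). The co-stimulatory ligand Cd80 was at 13.7 against 59.8 CPM, log2 fold -2.12 (-2.42 to -1.85). Il1a was at 31.7 against 131 CPM, log2 fold -2.04 (-2.23 to -1.86). Plet1 (ENSMUSG00000032068, chromosome 9, 50494525 to 50505482), a surface glycoprotein, was at 12.4 against 228 CPM, log2 fold -4.19 (-4.50 to -3.92). Type I interferon genes had 10 of 14 higher (median 1.20) and interferon-gamma genes 9 of 14 higher (median 0.66), with the T cell chemokine Cxcl9 at 31.3 against 12.4 CPM, log2 fold 1.34 (1.08 to 1.60). Ifit2 (ENSMUSG00000045932, chromosome 19, 34550694 to 34576419) was at 19.6 against 4.18 CPM, log2 fold 2.23 (1.84 to 2.64), though -0.07 in male and 3.43 in female cells. All 16 acinar carry-over genes were higher (median 3.99).

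With the combination, macrophages had lower matrix enzymes and chemokines than in vehicle: matrix remodelling enzymes had 8 of 10 lower (median -2.07), chemokines 9 of 13 (median -0.91), hypoxia and glycolysis genes 11 of 12 (median -1.28) and dendritic cell activation genes 6 of 11 (median -1.31). The collagen list lay at -3.25 (-3.12 with absent genes at the bound of their interval). Carried-over stromal RNA was not separated from a change in macrophages for the matrix enzyme values here. Mmp12 was at 80.0 against 919.8 CPM, log2 fold -3.52 (-3.66 to -3.39). Plet1 was at 4.51 against 228 CPM, log2 fold -5.63 (-6.26 to -5.11). Dcstamp (ENSMUSG00000022303, chromosome 15, 39745930 to 39760938), needed for macrophage fusion, was at 10.5 against 103 CPM, log2 fold -3.29 (-3.68 to -2.93), and the angiogenic factor Vegfa at 29.4 against 90.3 CPM, log2 fold -1.62 (-1.85 to -1.40). Lyve1 (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239), a hyaluronan receptor, was at 176 against 24.4 CPM, log2 fold 2.85 (2.69 to 3.01). Vsig4 (ENSMUSG00000044206, chromosome X, 96247203 to 96293438), a complement receptor, was at 80.0 against 5.11 CPM, log2 fold 3.96 (3.65 to 4.30). The haemoglobin scavenger receptor Cd163 was at 74.8 against 19.0 CPM, log2 fold 1.98 (1.77 to 2.18). The alternative macrophage list, which holds Lyve1 and Cd163, had 4 of 14 higher and 4 lower (median -0.34). Interferon-gamma genes had 8 of 14 higher (median 0.75) with Cxcl9 at 35.7 against 12.4 CPM, log2 fold 1.53 (1.26 to 1.80), and Ccl5, which attracts T cells, was at 154 against 34.4 CPM, log2 fold 2.16 (2.02 to 2.31). Against FAKi alone, matrix remodelling enzymes lay at -1.89 and chemokines at -0.71. Against MEKi alone, type I interferon genes lay at -0.91 (10 of 14 lower), though at 0.26 in male cells, and ERK output genes at 0.60, though at -0.24 with cells thinned to equal depth or in male cells alone. Departures from the sum of single agents, whose folds again share the single vehicle library, were -0.06 for matrix remodelling enzymes and 0.21 for chemokines. They were -0.43 for type I interferon, 0.40 for ERK output and 1.55 for the cell cycle.

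**Figure D3:**
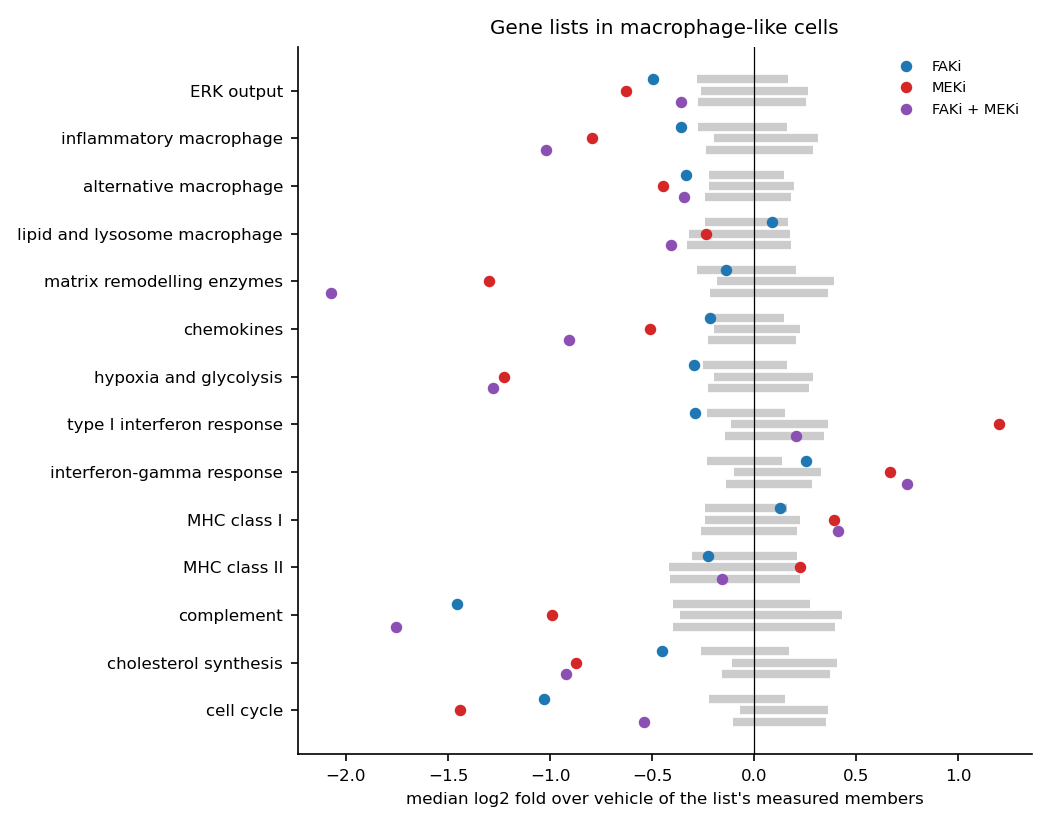
Median log2 fold over vehicle (horizontal axis) of gene lists in macrophage-like cells, as dots for FAKi (blue), MEKi (red) and the combination (purple), with grey bars over the central 95% of matched random lists. Hypoxia and glycolysis genes lie at -1.23 under MEKi and -1.28 under the combination against -0.30 under FAKi.

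Neutrophils (118 vehicle, 1109 FAKi, 101 MEKi and 141 combination cells) were compared in the same way. Under FAKi, neutrophil granule genes, made during maturation in marrow, had 8 of 11 members lower (median -1.34, -1.01 in male cells). Ngp (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012) was at 158 against 5229 CPM, log2 fold -5.05 (-5.18 to -4.91). Ltf (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767), lactoferrin, was at 104 against 1629.8 CPM, log2 fold -3.97 (-4.16 to -3.80). Camp (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617), cathelicidin, was at 286 against 3912 CPM, log2 fold -3.78 (-3.89 to -3.67); in male cells the log2 folds were -3.65, -3.30 and -0.79. Chemokines were higher under FAKi (8 of 8, median 1.79, 1.82 in male cells), with Ccl3 at 2297 against 602 CPM, log2 fold 1.93 (1.78 to 2.08) and Ccl4 at 1478 against 305 CPM, log2 fold 2.27 (2.07 to 2.49), as were hypoxia and glycolysis genes (9 of 11, median 1.31) and lipid and lysosome genes (6 of 11, median 1.18). MHC class II genes had 5 of 7 higher (median 0.84, 0.26 in male cells) and the antigen-presenting CAF list 6 of 7 (median 1.04, 0.49 in male cells). Neither was particular to FAKi. MHC class II genes lay at 0.70 under MEKi (3 of 5 higher) and 0.96 under the combination (4 of 5). The antigen-presenting CAF list lay at 0.71 (4 of 6 higher, 1 lower) and 0.99 (5 of 6 higher, 1 lower). Hilpda, a lipid droplet protein induced by hypoxia, was at 896 against 149 CPM, log2 fold 2.58 (2.30 to 2.90). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) was at 116 against 15.8 CPM, log2 fold 2.81 (1.98 to 3.95). MEKi also went with higher hypoxia and glycolysis genes (median 0.74) and chemokines (4 of 6, median 1.53), with Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355) at 3167 against 602 CPM, log2 fold 2.39 (2.23 to 2.56). Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683) was at 1897 against 305 CPM, log2 fold 2.63 (2.41 to 2.87). Under the combination chemokines lay at -0.04 and hypoxia and glycolysis genes at 0.87 (6 of 11 higher), though the latter lay at -0.04 in female cells. Tpi1 (ENSMUSG00000023456, chromosome 6, 124810586 to 124814296), a glycolytic enzyme, was at 455 against 104 CPM, log2 fold 2.11 (1.74 to 2.53). Il1a (ENSMUSG00000027399, chromosome 2, 129299610 to 129309972) was at 102 against 628 CPM, log2 fold -2.61 (-2.99 to -2.26). All 16 acinar carry-over genes measured were higher under the combination (median 7.26, 6.12 with absent genes at the bound of their interval) and all 6 under MEKi (median 4.36, 3.86 at the bound). Against FAKi alone, granule genes under the combination were higher (8 of 11, median 1.60) and chemokines lower (6 of 8, median -1.38).

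Across all T-like cells (4287 vehicle, 6621 FAKi, 6407 MEKi and 3619 combination), interferon genes parted the treatments. The arms lay in different clusters: clusters 7 and 10 held 51.1% and 35.2% of vehicle T cells, clusters 4 and 2 50.9% and 26.6% under FAKi, and clusters 3 and 2 42.8% and 31.9% under MEKi and 34.7% and 29.6% under the combination. Clusters 2, 3 and 4 held 36, 51 and 8 vehicle cells, too few for a comparison with vehicle inside them. Type I interferon genes had 12 of 14 members higher under MEKi (median 1.20), 7 lower under FAKi (median -0.60, -0.93 in male cells) and 9 lower under the combination (median -0.79). Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), an antiviral enzyme, was at 34.5 against 8.17 CPM, log2 fold 2.08 (1.89 to 2.27) under MEKi, and Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009) at 11.2 against 38.3 CPM, log2 fold -1.78 (-1.96 to -1.60) under the combination. Against MEKi alone, all 14 members were lower in the combination (median -1.90). Interferon-gamma genes had 8 of 13 higher under MEKi (median 0.79) and 2 higher under the combination (median 0.40). Cytotoxicity genes had 6 of 10 higher under MEKi (median 0.83) and 6 under the combination (median 1.15), against 2 under FAKi (median 0.11). The chemokine Ccl5, made by effector T cells, was at 336 against 93.1 CPM, log2 fold 1.85 (1.79 to 1.91) under MEKi and 366 against 93.1 CPM, log2 fold 1.98 (1.92 to 2.04) under the combination, and the protease Gzmb at 12.1 against 4.21 CPM, log2 fold 1.52 (1.24 to 1.82) under the combination. The chemokine list, which does not hold Ccl5, had 11 of 13 lower under MEKi (median -1.59), and 10 lower and 1 higher under the combination (median -2.37). It made up 0.0081% of vehicle T cell UMIs. Carry-over genes of other cells shifted too. Immune ones, mostly myeloid, had 5 of 10 lower under MEKi (median -0.69), and 6 lower and 1 higher under the combination (median -1.22). Epithelial ones had 11 of 12 lower (median -3.14) and 10 lower (median -2.08). Acinar ones had 11 of 16 higher and 2 lower (median 1.82), and 15 higher (median 3.14). Carried-over RNA was not separated from a change in T cells. Under the combination the inhibitory receptor Lag3 was at 6.87 against 1.88 CPM, log2 fold 1.86 (1.45 to 2.30). Il2ra was at 47.0 against 18.7 CPM, log2 fold 1.33 (1.19 to 1.47). Cell cycle genes had 10 of 19 higher under FAKi (median 0.76), 11 under MEKi (median 0.81) and 4 under the combination (median 0.46). ERK output genes lay at -0.52 under MEKi (5 of 13 lower, 2 higher) and -0.42 under the combination (3 lower, 3 higher, 7 within 1.5-fold). Under FAKi they lay at -0.07 (0.25 in male cells). Immediate early genes, which dissociation can induce, lay at -0.12 under MEKi and 0.60 under the combination (7 of 14 higher, 0 lower). Under FAKi the heat shock genes Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238) and Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) were at 79.3 against 11.3 CPM, log2 fold 2.81 (2.66 to 2.97) and 43.2 against 6.53 CPM, log2 fold 2.72 (2.52 to 2.94). Both belong to the immediate early and dissociation stress list, which had 4 of 14 higher and 5 lower under FAKi (median 0.02). Scaling by trimmed means moved the median of all genes in T cells by -0.14, -0.25 and -0.13 for FAKi, MEKi and the combination. In CD8 T cells it moved by -0.13, -0.26 and -0.11, in B cells by up to -0.20 and in macrophages by up to -0.14. No checked list median that was at least 1.5-fold and outside the random lists reversed under that scaling. Smaller medians within reach of the shift, such as 0.11 for cytotoxicity genes in T cells under FAKi, may change sign. B cell lists were not checked.

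CD8 T cells also lay in different clusters of the T and NK cells: clusters 9 and 10 held 51.2% and 43.1% in vehicle, cluster 3 86.0% under FAKi, and cluster 2 60.0% under MEKi and 77.5% under the combination. In CD8 T cells the cytotoxicity list had 8 of 10 members higher under MEKi (median 1.89), 7 of 10 under the combination (median 1.32) and 4 of 8 under FAKi (median 0.64, 0.34 in male cells). With classes named without digestive-enzyme genes the combination held 1710 CD8 T cells in place of 1082, and the cytotoxicity median was 1.17. Carry-over genes of other cells differed as well. All 16 acinar genes were higher under MEKi and under the combination (medians 6.10 and 6.82) and all 4 haemoglobin genes under FAKi and MEKi (medians 8.17 and 8.48). Of the immune carry-over list, mostly myeloid genes, 6 of 10 were lower under MEKi (median -0.82) and 7 under the combination (median -1.73). Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) was at 945 against 192 CPM, log2 fold 2.30 (2.24 to 2.36) under the combination, the granzymes Gzma and Gzmb were at 25.5 against 1.01 CPM, log2 fold 4.61 (3.89 to 5.54) and 6.45 against 1.16 CPM, log2 fold 2.44 (1.71 to 3.34) under MEKi, and Gzmb at 7.80 against 1.16 CPM, log2 fold 2.72 (1.96 to 3.63) under the combination. Tox, a factor of T cell exhaustion, was at 33.8 against 73.3 CPM, log2 fold -1.12 (-1.30 to -0.94) under FAKi and 38.8 against 73.3 CPM, log2 fold -0.92 (-1.09 to -0.75) under the combination, while the receptor Pdcd1 (PD-1) was at 3.54 against 0.939 CPM, log2 fold 1.88 (0.95 to 2.96) there. Type I interferon genes lay at 1.34 under MEKi (13 of 14 higher), -0.30 under FAKi and -0.36 under the combination. A cluster of CD8 T cells led by Ifit1, Isg15 and Rsad2 held 24.5% of the MEKi CD8 cells (507 cells).

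B cells (3545 vehicle, 5718 FAKi, 3991 MEKi and 2719 combination) held more cell cycle RNA in every treated library: 14 of 19 members were higher under FAKi (median 0.87), 19 under MEKi (median 1.12) and 19 under the combination (median 1.94). Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), a marker of dividing cells, was at 116 against 36.6 CPM, log2 fold 1.66 (1.54 to 1.78), 146 against 36.6 CPM, log2 fold 2.00 (1.88 to 2.11) and 176 against 36.6 CPM, log2 fold 2.27 (2.16 to 2.38) under FAKi, MEKi and the combination. The arms lay in different clusters: cluster 5 held 89.5% of vehicle B cells, cluster 0 92.7% under FAKi, and cluster 1 77.2% under MEKi and 71.8% under the combination. Cluster 17, with Mki67 and Top2a among its leading genes, held 59, 224, 162 and 236 cells. With classes named without digestive-enzyme genes the combination held 4186 B cells in place of 2719, and the cell cycle median was 1.49 in place of 1.94. The shares below were taken on the 2719 cells. With cells thinned to 1000 UMIs, 8.66% (7.75 to 9.63) of vehicle B cells held at least 2 UMIs of the cell cycle list, against 9.95% (9.19 to 10.8), 11.6% (10.6 to 12.6) and 14.3% (13 to 15.7) under FAKi, MEKi and the combination. At 4 UMIs, an alternative to the main rule of 2, the shares were 1.55%, 2.62%, 2.88% and 6.07%. The neutrophils of the 4 libraries, mature cells that seldom divide, held at least 2 such UMIs in 14.4%, 19.7%, 20.8% and 22.0% of cells and at least 4 in 2.54%, 2.16%, 7.92% and 4.26%, with median depths of 3713, 2508, 2956 and 3796 UMIs against 4801, 3015, 4126 and 5009 in B cells. The neutrophil shares at 4 UMIs rest on 3, 24, 8 and 6 cells. In CD8 T cells of the same libraries, with median depths of 8432, 5130, 6759 and 8268.5 UMIs, the shares were 3.93%, 5.16%, 7.77% and 6.19% at 2 UMIs and 0.0644%, 0.167%, 0.868% and 0.277% at 4. ERK output genes were lower under MEKi (10 of 13, median -0.90) and under the combination (9 of 13, median -0.96), with the ERK-induced factor Egr1 at 39.2 against 126 CPM, log2 fold -1.69 (-1.80 to -1.57) under MEKi and 51.4 against 126 CPM, log2 fold -1.29 (-1.40 to -1.19) under the combination. Immediate early genes, which dissociation can induce and which include Fos, had 7 of 14 lower under FAKi (median -0.61, -0.18 in male cells), 7 under MEKi (-0.62, -0.26 in male cells) and 8 under the combination (-0.67, -0.24 in male cells). Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) was at 95.6 against 443 CPM, log2 fold -2.21 (-2.28 to -2.15) under FAKi. Type I interferon genes lay at -0.63 under FAKi, 1.32 under MEKi and -0.99 under the combination.

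**Figure D4:**
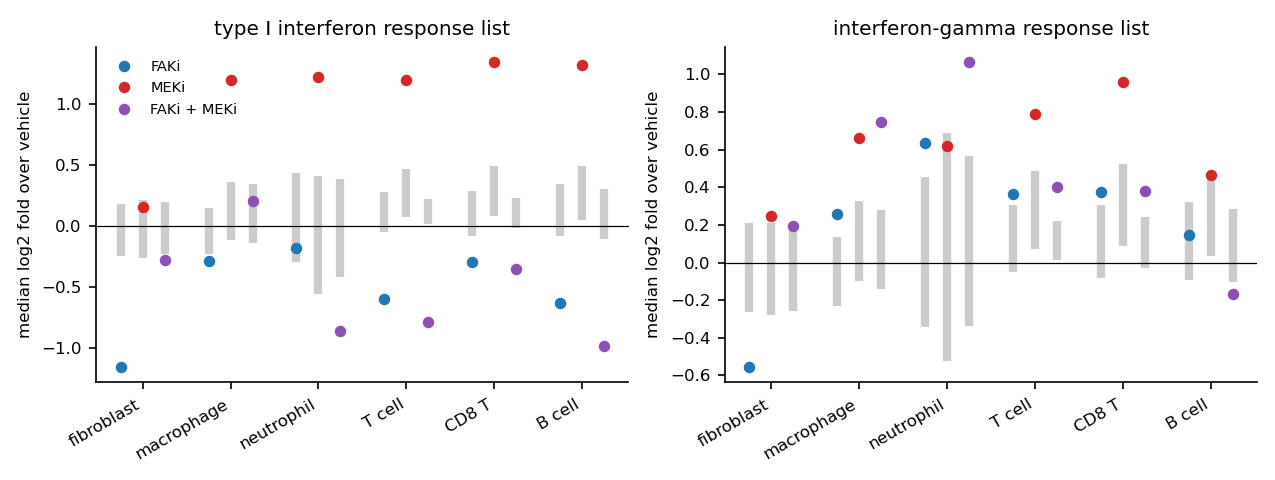
Median log2 fold over vehicle (vertical axis) of the type I interferon and interferon-gamma lists in 6 cell classes, as dots for FAKi (blue), MEKi (red) and the combination (purple), with grey bars over the central 95% of matched random lists. Type I interferon genes lie at 1.20 in T cells, 1.32 in B cells and 1.20 in macrophages under MEKi, against -0.79, -0.99 and 0.20 under the combination.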

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

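Tests of the shared shift between vehicle and treated libraries, of sex, of single mice, of fibroblast clusters and of the combination in T cells were chosen only after the result was seen; for free RNA and for gene copies in the inflammatory CAF list, what each explanation predicts was written before the value was seen. The list without copies is itself an alternative added after the data were seen.

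Inflammatory CAF genes were lower in FAKi fibroblasts (median log2 fold -1.53). The larger share of male cells in the FAKi library is argued against by male cells alone, which gave -1.27, and reads shared between gene copies by the list without such genes, which gave -1.52. A different mix of fibroblast clusters stays open. Within the 3 largest clusters the medians ranged from -0.74 to -0.39, so a part of the difference may lie between clusters. The clusters were themselves built in part from these genes. These clusters (0, 1 and 2) held only 106, 493 and 297 of the 4660 vehicle fibroblasts, so the medians cover a small part of the vehicle cells. A response of fibroblasts to the inhibitor also stays open, as does a difference between pools of mice, since each arm is a single pool.

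Type I interferon genes were higher under MEKi in T cells, B cells, macrophages and neutrophils (median 1.23, 5 of 9 members higher and 1 lower in neutrophils). Cells of a single mouse are argued against by female and male cells, which come from different mice and gave 1.43 and 1.08 in T cells and 1.21 and 1.19 in B cells. In macrophages they gave 1.55 and 0.55, with Ifit2 at 3.43 and -0.07, so there cells of a single mouse are not excluded. Male cells turned the macrophage median of the combination over MEKi from -0.91 to 0.26. Free RNA in the droplets would add alike to every class, but the excess in UMIs of the list per cell was 1.13 in B cells, 3.05 in T cells, 3.26 in macrophages and 0.311 in neutrophils, a ratio of 10.5 between the highest and the lowest. Neutrophils held fewer UMIs per cell under MEKi, which lowers their excess. With vehicle scaled to the MEKi depth of each class, a step added after the data were seen, the excess was 1.23, 3.86, 5.60 and 1.38 in the same order, a ratio of 4.54. A MEK inhibitor response that does not depend on FAK predicts higher genes in the combination too, where the T cell median was -0.79. B cells and neutrophils also lay below vehicle there, and macrophages slightly above it. The combination is 1 pool, so a difference between pools could hide such a response, and these values cannot exclude it. A difference between the pools, or a response to MEK inhibition that FAK inhibition does or does not remove, could account for the higher genes under MEKi. These cannot be told apart with 1 library per arm.

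In 4 cell classes 13 genes were higher and 8 lower in all 3 treated libraries than in vehicle, of 9833 tested. Of these 21 genes 85.7% had a near-identical copy elsewhere in the genome, against 7.54% of expression-matched genes, so a candidate source is a difference in how reads shared between copies were assigned in the vehicle libraries. The 14.3% without a copy, Saa3, Pdf and Coro1b, stay open between a response to treatment and a library difference. For Saa3 in T and B cells carried-over RNA is open as well. In vehicle it was at 1580 CPM in macrophages against 41.3 in T cells and 54.9 in B cells, beyond the carry-over ratio of 10. Batch and read length are not given in the sources used here.

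Differences from vehicle of opposite direction between cell classes were found for these lists. They were not tested, and with 1 pool per arm a difference between pools is not separable from treatment. Under FAKi the antigen-presenting CAF list, most of whose measured members in T cells are MHC class II genes, had a median log2 fold of -1.37 in fibroblasts and 0.63 in T cells. Lists of other cells also lay higher in FAKi T cells: immune carry-over at 0.56 (4 of 10 higher), neutrophil granule at 1.27 (6 of 8 higher, 1 lower) and lipid and lysosome macrophage at 0.56 (5 of 11 higher). Acinar carry-over genes went the other way, with 13 of 15 lower. Carried-over RNA was not separated from a change in T cells. For the cell cycle list under FAKi the medians were -0.91 in fibroblasts, -1.03 in macrophages and 0.76 in T cells, and under MEKi -1.44 in macrophages and 0.81 in T cells. The thinned share of cells with at least 2 UMIs of that list did not show the opposition for fibroblasts and T cells under FAKi, with 5.99% against 5.72% in vehicle and 8.26% against 6.95%. At 4 UMIs, an alternative, the directions were opposite, with 0.289% against 0.888% in fibroblasts and 1.31% (1.05 to 1.62) against 0.980% (0.707 to 1.32) in T cells, whose intervals overlap. At 2 UMIs in macrophages it was 9.63% under FAKi and 7.95% under MEKi against 11.6%, and in T cells 9.74% under MEKi. Male cells made up 98.1% of the sexed cells in the FAKi CAF library and 99.7% in the FAKi immune library, although the labels describe both sexes. Digestive-enzyme RNA of acinar cells made up 0.177% of B cell UMIs and 0.0820% of fibroblast UMIs in the combination libraries and 0.0837% of B cell UMIs under MEKi, above the level in vehicle. In neutrophils it was 0.928% and in T cells 0.238% in the combination library, and in T cells 0.0698% under MEKi against 0.0614% in vehicle.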

How the results depend on the processing

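Clustering and naming without digestive-enzyme genes and lists without near-identical copies were chosen only after the data were seen; all other alternatives were planned. No paired analysis was possible because each group is a single pooled library with no label that links mice across groups, and for the same reason no library could be left out. Of 149 alternative values for the ERK output medians over vehicle, 144 counted as unchanged and 5 as moved. All other list medians, among them the interferon, contractile and cytotoxicity lists, gave 3421 alternative values. Of these, 3252 counted as unchanged, 146 as moved and 23 as reversed. The labels do not track sign alone: T cell ERK output under FAKi, at 0.25 in male cells against -0.07, counted as moved. Of share ratios, 44 of 61 stayed for fibroblasts, macrophages and neutrophils and 230 of 301 for the rest. Of shares of cells 324 of 492 stayed. Cycle ratios stayed in 4 of 9 for fibroblasts and 19 of 42 for the rest. Departures from additivity stayed in 7 of 7 for ERK output and 109 of 122 for the rest. Scaling by TMM, stricter filters, the mean of per-cell CPM and lists without near-identical copies reversed none of these list medians. Depth limits small classes most: neutrophils had 101 cells under MEKi and macrophages 241 under the combination. For the values that follow, medians are log2 folds, the first value is the alternative and the one after "against" the value reported; the cause was not tested.

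Fibroblast clusters 0, 1 and 2 held only 106, 493 and 297 of the 4660 vehicle fibroblasts, so values within them cover few vehicle cells. Within single fibroblast clusters, ERK output genes (combination over vehicle) were at -0.20 in cluster 0 and -0.026 in cluster 2, against -0.62. In cluster 0 immediate early genes (combination over vehicle) were at -0.37 against 0.63, basement membrane genes (combination over FAKi) at -0.017 against 0.66, MHC class II genes (FAKi over vehicle) at 0.036 against -1.10, complement genes (combination over FAKi) at -0.29 against 0.75, and cholesterol synthesis genes at 0.053 against -1.09 (MEKi over vehicle) and 0.41 against -0.70 (combination over vehicle). Cell cycle genes, combination over vehicle, were at 0.24 in cluster 0 and 0.091 in cluster 2 against -2.04; combination over FAKi they were at 0.19, 0.12 and 0.044 in clusters 0, 1 and 2 and at 0.073 in female cells, against -1.03. In cluster 2 contractile genes (combination over FAKi) were at 0.40 against -0.96 and chemokines (combination over vehicle) at 0.029 against -1.64. T cell cytotoxicity genes (combination over FAKi) were at -0.44 in cluster 3 and -0.55 in cluster 4, against 0.81.

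By sex or thinning, macrophage ERK output genes (combination over MEKi) were at -0.24 thinned and -0.24 in male cells, against 0.60, and type I interferon genes at 0.26 in male cells against -0.91. In neutrophils (combination over vehicle) ERK output genes were at -1.04 in female and -0.44 in male cells against -0.63, hypoxia genes at -0.040 in female cells against 0.87 and type I interferon genes at 0.91 in female cells against -0.86. T cell ERK output genes under FAKi were at 0.25 in male cells against -0.07, and CD8 exhaustion genes under FAKi at 0.47 with a list minimum of 1 UMI and 0.88 in male cells, against -0.74.

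Log2 ratios of shares over vehicle moved as follows. Fibroblasts under FAKi were at 0.18 (female), 0.27 (male) and 0.24 (resolution 2) against 0.33; under MEKi at 0.35, 0.34, 0.32 and, with the looser filter, 0.49 against 0.42; under the combination at 0.36, 0.31, 0.31 and 0.47 against 0.41. Macrophages under FAKi were at 0.53 (male) and -0.25 (resolution 2) against -0.09, under MEKi at -1.43 (male) against -1.24, and under the combination at -2.14 (female) against -1.87. Neutrophils under the combination were at -0.69 (female) and 0.83 (male) against 0.03, plasmacytoid dendritic cells under FAKi at 0.61 (male) against -0.66, and B cells under the combination, without digestive-enzyme genes, at 0.0092 against -0.61. Regulatory T cells under FAKi were at 1.25 (resolution 0.5), 0.63 (resolution 2) and 0.82 (without digestive-enzyme genes) against -2.46, and under MEKi at 0.48 (resolution 0.5) and 0.20 (without those genes) against -0.93. Fibroblasts in cycle were at -0.29 unthinned and -1.62 with at least 4 UMIs against 0.07 under FAKi, at -0.17 and -1.76 against 0.05 under MEKi, and at -2.75 with at least 4 UMIs against -0.09 under the combination.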

Other observations

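Genes induced by glucocorticoids stood above vehicle in several treated classes. Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527) was at 127 against 29.9 CPM, log2 fold 2.09 (1.96 to 2.23) in macrophages, 117 against 30.2 CPM, log2 fold 1.96 (1.86 to 2.06) in T cells and 85.4 against 18.9 CPM, log2 fold 2.18 (2.02 to 2.34) in B cells under FAKi. In fibroblasts Tsc22d3 had a log2 fold of 2.57 (2.52 to 2.62) under FAKi, Pdk4 of 2.65 (2.47 to 2.84) under the combination, and Zbtb16 of 2.94 (2.83 to 3.06), 2.87 (2.75 to 2.99) and 3.64 (3.53 to 3.76) under FAKi, MEKi and the combination. No list of such genes was fixed, and the grouping was made after the values were seen.

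In B cells of the combination library S1pr2 (ENSMUSG00000043895, chromosome 9, 20962361 to 20976781), a receptor that keeps cells in the follicle, was at 28.4 against 2.76 CPM, log2 fold 3.35 (2.97 to 3.78), and Gcsam (ENSMUSG00000022659, chromosome 16, 45610380 to 45622867), a signalling protein of germinal centre B cells, at 34.7 against 3.82 CPM, log2 fold 3.17 (2.85 to 3.54). Both were picked after the values were seen. Eaf2 (ENSMUSG00000022838, chromosome 16, 36792884 to 36875003) was at 29.5 against 8.71 CPM, log2 fold 1.76 (1.52 to 2.00) under MEKi. In T cells, haemoglobin carry-over genes lay above vehicle in all treated libraries, with list medians of 8.64, 8.08 and 7.60.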
